A study of Mus musculus with 9 samples.

How the data were processed

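Total RNA from SV40-immortalized mouse embryonic fibroblasts was labelled with biotin and hybridized to an Affymetrix mouse array, per the labels. The series holds 9 arrays. Cells with an empty expression vector (MEF-V) were the control, and the other groups expressed human HMGN2 (MEF-N2) or human HMGN4 (MEF-N4), with 3 arrays in each of the 3 groups. The labels number the arrays of a group as biological replicates and do not say whether these were separate cultures or separate transductions, so the p-values measure only the spread between these samples.

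The deposited values are on a log2 scale, 1 per probe set and array, as their range shows. The submitters name Partek 6.5, and its role, the background correction, the normalization and the summary of probes into probe sets are not given in the sources used here. The medians of the 9 arrays lay between 7.29 and 7.41, but MEF-N4 replicate 3 had an interquartile range of 3.13, against 3.37 to 3.50 in the others. Whether the arrays had been normalized to each other could not be told. No detection calls were used here, so the distance of dim genes from background could not be set and the number of arrays limits the precision.

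The table held 241576 probe sets, most of them at the level of exons. Of these, 212097 named exactly 1 gene symbol, 4475 named several and 25004 named none. Older symbols were brought up to date, which changed 2742 of them. The probe sets that named 1 gene were averaged on the log2 scale, giving 20352 genes with a median of 8 probe sets each. Genes whose mean over the 9 arrays lay under the 25th percentile were left out, and 15264 were tested. The genome build behind the array annotation is not given in the sources used here, so no coordinates are printed, and chromosomes and gene order were taken from a separate gene table.

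All 9 arrays entered 1 linear model in limma 3.58.1 under R 4.3.3, with moderated variances and 3 contrasts of group means. P-values were adjusted by the Benjamini-Hochberg method over the tested genes of each contrast, and genes were called at a threshold of 0.05. A moderated F test asked which genes differed among the 3 groups. Gene lists, 34 in all, covered chromatin and DNA repair, the cell cycle, matrix and contractile genes, stress and metabolic pathways, and markers of other cell types. The lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01 and with the correlation estimated from the data. The rotation test fry was run beside it, and all list p-values were adjusted over the lists of a comparison. A list of Xist and Y-linked genes had no member above the filter and was not tested.

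The genes named were chosen by a rule set before the data were examined, as were the lists, the main tests and the alternatives. Tests chosen after a result was seen are named in the closing sections, as is the later choice of method for the array weights. For each comparison the rule took called genes whose 2 groups did not overlap on any array, leaving out predicted gene models, and named the 10 largest rises and the 10 largest falls. It added, from each list, up to 4 called members, or the 2 with the largest change where none was called. Hmgn1, Hmgn2, Hmgn3 and Hmgn5 were always named. Atm, Atrx and Brca2 were always named because the published study of these cells is remembered to have discussed them, so these 3 are not an independent choice.

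The shared response was measured as the Pearson correlation across genes of the changes in MEF-N2 and MEF-N4, beside 200 simulations. In these, unchanged groups were set against a shared simulated control, with the same spread per gene in all 3 groups. Chromosome shifts compared the median change of a chromosome's genes with all tested genes by 100000 permutations of genes over chromosomes, two-sided, and windows of 50 neighbouring genes were tested against the largest window of each of 1000 permutations. The 95% intervals of class medians came from 10000 draws of genes with replacement. These steps and the drawings used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

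The alternatives were a replicate block, quantile normalization, median centring, no filter, a filter at the 50th percentile, the brightest or the median probe set of a gene, each probe set tested on its own, a trended and robust variance, only the 6 arrays compared, array weights, an adjusted p threshold of 0.1, a minimum of 1.5-fold, and each array left out in turn. The default fit of the array weights did not converge, and the weights came from limma's gene-by-gene method. Other groupings of the arrays were counted for each comparison.

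The procedure was tested on simulated data with the spread per gene pooled over these arrays. In a simulated comparison of MEF-N4 with MEF-V, limma recovered 58.21% of genes changed by 1.5-fold, 98.51% of those changed by 2-fold and 100% of those changed by 3-fold, with 9 false calls among the genes left unchanged. A list of 37 genes raised by 0.3 on the log2 scale was found, and 0 lists passed where no gene was changed. The correlation between genes was not simulated. All simulated arrays had the same spread, while weights of the real arrays ran from 0.11 for MEF-N4 replicate 3 to 3.508 for MEF-N4 replicate 1. The rates found need not hold for the real arrays.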

Results

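Gene expression was measured on 9 Affymetrix mouse arrays, 3 for each of 3 lines of SV40-immortalized mouse embryonic fibroblasts, cells kept dividing by a viral T antigen. The cells carried an empty vector (MEF-V, the control), human HMGN2 (MEF-N2) or human HMGN4 (MEF-N4). HMGN proteins are small proteins that bind nucleosomes, the units of chromatin, and the mouse has no Hmgn4 gene. Deposited log2 values ran from 3.45 to 15.21, with array medians between 7.29 and 7.41. Of 20352 genes, 15264 passed the filter on dim genes. The number of arrays limits the precision of each value.

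Replicate 3 of MEF-N4 stood apart from the other arrays. Its median correlation with the other 8 arrays was 0.921, and the same median for each of those arrays ran from 0.973 to 0.980. The interquartile range of its probe set values was 3.13, against 3.37 to 3.50 in the others. Its values for several gene groups are given below beside those of the other MEF-N4 arrays.

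Values read for mouse Hmgn genes differed between the groups. The mean over the 4 probe sets annotated to Hmgn2 (NCBI Gene 15331, chromosome 4) rose in MEF-N2 by 0.51 ± 0.10 on the log2 scale (SE, n = 3 arrays per group). This was 1.43-fold, with a limma adjusted p of 0.0309. Of its 4 probe sets, 1 was called: probe set 10517144 rose by 1.94 ± 0.22 (SE, n = 3), 3.84-fold, adjusted p = 0.0396 over probe sets, and stood at 0.28 above MEF-V in MEF-N4. The others stood at 0.40, −0.15 and −0.14 in MEF-N2 against MEF-V. The numbers of these 4 probe sets lie far apart, while those of Hmgn1 and of Hmgn3 run in sequence. Probe set numbers follow gene position within a chromosome, so some of the 4 may read other loci. The mean and the brightest probe set of Hmgn2 are therefore not sure readings of the chromosome 4 gene. Whether probe set 10517144 reads the human transcript was not analysed here, so a rise of the mouse gene itself is not shown. The array has no probe set for human HMGN4. In MEF-N4 the mean over the 4 Hmgn2 probe sets stood at −0.10 against MEF-V, adjusted p = 0.532, and it was 0.61 lower than in MEF-N2, adjusted p = 0.00523. Hmgn5 fell in MEF-N4 by 1.32 ± 0.18 (SE, n = 3), adjusted p = 0.00104, and stood at −0.75 in MEF-N2, adjusted p = 0.0748. Hmgn3 fell in MEF-N4 by 0.60, adjusted p = 0.033, and Hmgn1 was not called in any comparison, with −0.07 in MEF-N4, 0.10 in MEF-N2 and −0.17 between them. The Hmgn2 call in MEF-N2 was lost without any of the 3 MEF-V arrays, any of the 3 MEF-N2 arrays or MEF-N4 replicate 1, with adjusted p up to 0.205, and the Hmgn3 call in MEF-N4 was lost without MEF-V replicate 2 or 3, MEF-N4 replicate 1 or any MEF-N2 array, with adjusted p up to 0.205. With the brightest probe set in place of the mean, the difference in Hmgn2 between MEF-N4 and MEF-N2 was −0.18 and was not called.

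**Figure D1:**
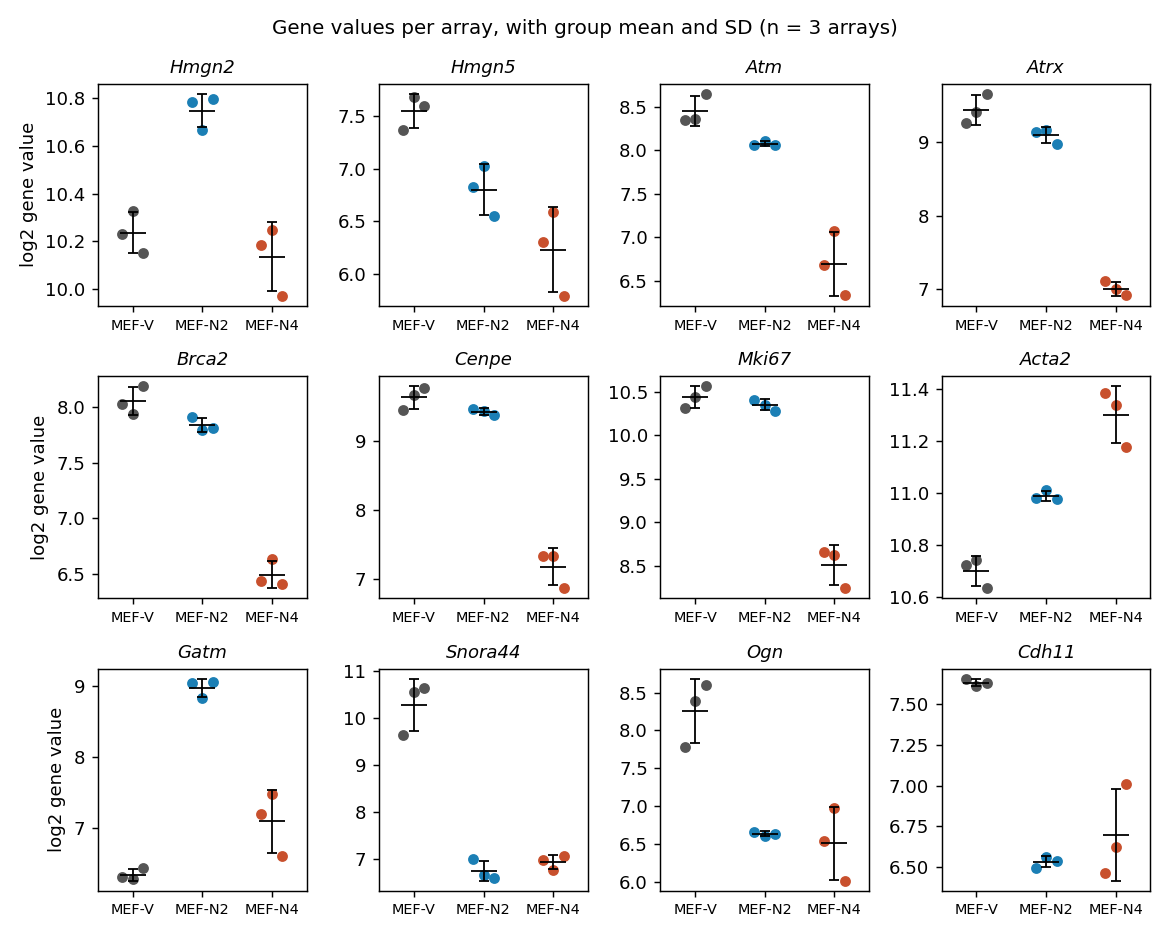
Log2 values of 12 named genes on each array (vertical axis, log2 gene value), by group (horizontal axis), with 1 point per array, a bar at the group mean and whiskers of 1 SD over 3 arrays; the vertical axes differ between panels and do not start at 0. Atrx had a mean of 9.44 in MEF-V, 9.10 in MEF-N2 and 7.005 in MEF-N4, and Gatm had 6.34, 8.98 and 7.10.

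Comparing MEF-N4 with MEF-V asks what changed in cells that make human HMGN4. More genes were called lower than higher, 654 against 60, but with array weights 1628 were lower and 1813 higher. In that fit MEF-N4 replicates 1, 2 and 3 had weights of 3.508, 0.574 and 0.11, so it rested mostly on replicate 1 for MEF-N4. Cenpe, a kinetochore motor, fell by 2.46 ± 0.13 on the log2 scale (SE, n = 3), 5.50-fold, and Nipbl, which loads cohesin, fell by 2.40, 5.29-fold. Thoc2 of the mRNA export complex fell by 2.39, Vps13a, a lipid transfer protein, fell by 2.30, Rif1, a regulator of replication timing and break repair, by 2.25, Ranbp2 of the nuclear pore by 2.22 and Kif20b, a mitotic kinesin, by 2.20. The widest fall was of Snora44, a small nucleolar RNA, which fell by 3.34 ± 0.22 (SE, n = 3), 10.1-fold. Rex2, read by 1 probe set, fell by 2.64 to a mean of 4.895 in MEF-N4, so dim that the size of this fall is not exact. Adjusted p-values of these 9 genes ran from 4.96e-07 to 8.23e-05, and each of the 9 was lower in all 3 MEF-N4 arrays than in all 3 MEF-V arrays.

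Atrx, Atm and Brca2 fell in MEF-N4. Atrx (NCBI Gene 22589, X chromosome), a chromatin remodeller, fell by 2.44 ± 0.12 on the log2 scale (SE, n = 3), 5.43-fold, adjusted p = 4.96e-07. Atm (NCBI Gene 11920, chromosome 9), a kinase of the DNA damage response, fell by 1.75 ± 0.16 (SE, n = 3), 3.37-fold, adjusted p = 3.99e-05. Brca2 (NCBI Gene 12190, chromosome 5), a DNA repair gene, fell by 1.56 ± 0.10 (SE, n = 3), 2.95-fold, adjusted p = 2.15e-06. Of the 37 probe sets of Atrx, 36 lay below 0 and 35 were at least 2-fold lower, with a median of −2.54. Represented by its brightest probe set, Atrx stood at −0.29 in this comparison, adjusted p = 0.428, while Atm and Brca2 were called under all alternatives run per gene.

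DNA repair and mitosis were the lists with the most members lower in MEF-N4. In the DNA repair list 12 of 53 tested genes fell and 0 rose, or 16 and 1 adjusted over the list alone; Atr fell by 1.46 beside the 3 genes above. The list passed camera at an adjusted p of 7.65e-09, and its adjusted p = 0.656 with an estimated correlation. Fry, which asks whether the members of a list move on balance in 1 direction, gave it an adjusted p of 0.0768. Of 37 mitosis genes 10 fell and 0 rose, the same counts adjusted over the list alone, with Mki67, a marker of dividing cells, lower by 1.93 ± 0.12 (SE, n = 3) and Cenpf by 1.86. Camera gave an adjusted p of 2.81e-07 for mitosis, and its adjusted p = 0.656 with an estimated correlation. The fry adjusted p for mitosis was 0.068, and fry passed no list in MEF-N4 against MEF-V. MEF-N4 replicate 3 lay lowest: the median DNA repair gene stood at 8.003, 8.30 and 7.79 in MEF-N4 replicates 1, 2 and 3, against 8.36, 8.22 and 8.40 in MEF-V, and the median mitosis gene at 9.74, 9.90 and 9.36, against 9.93, 9.71 and 9.83.

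Chromatin and growth control genes changed in smaller numbers. Of 55 chromatin modifiers and remodellers 4 fell and 0 rose, or 7 and 1 adjusted over the list alone: Setd2 by 1.15, Kdm6a by 0.86, Smarca5 by 0.85 and Tet2 by 0.58. Their camera adjusted p of 0.0317 became an adjusted p = 0.94 with an estimated correlation, and the list median of −0.08 turned to 0.02 with the brightest probe set and to 0.01 without MEF-N4 replicate 3. The 9 HMG proteins had 2 members lower and 0 higher, or 4 lower adjusted over the list alone, with a camera adjusted p of 0.0146 and adjusted p = 0.656 with an estimated correlation. Among 30 tumour suppressors Apc fell by 1.10 and Nf1 by 0.71, with the same 2 adjusted over the list alone, and among 36 DNA replication genes Pola1, a subunit of DNA polymerase alpha, fell by 1.46 and Ccne2 by 0.73, also the same 2 adjusted over the list alone. Cdkn1a, the p21 inhibitor of cell cycle kinases, rose by 0.56 ± 0.11 (SE, n = 3) and was the 1 called member of 23 p53 target genes by all genes and adjusted over the list alone. No core histone of 12 was called by limma under either adjustment, though 5 were lower at an unadjusted p under 0.05, and the camera adjusted p of 0.0133 for that list was an adjusted p = 0.656 with an estimated correlation. The chromatin modifiers had medians of 8.80, 8.99 and 8.41 in MEF-N4 replicates 1, 2 and 3, against 8.92, 8.88 and 9.02 in MEF-V. In the same order the core histones had 8.26, 8.555 and 8.14, against 8.37, 9.06 and 8.71, and the HMG proteins 9.76, 9.83 and 9.70, against 9.79, 10.01 and 9.99.

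Contractile genes were among the rises. Acta2, smooth muscle actin, rose by 0.60 ± 0.09 on the log2 scale (SE, n = 3), 1.52-fold, adjusted p = 0.00195, and Cnn1, calponin, rose by 0.63; 2 of 24 contractile and myofibroblast genes rose and 0 fell, or 3 and 0 adjusted over the list alone. The largest rise was of ND6, a mitochondrial gene read by 1 probe set, at 1.54 ± 0.32 (SE, n = 3), 2.91-fold, adjusted p = 0.0169. Gatm, an enzyme of creatine synthesis, rose by 0.76, and Mzf1, Actbl2, Osgep, Scn4b, Mrpl48 and Dio3 rose by 0.58 to 0.74. Of 20 fibroblast markers 4 fell and 0 rose, or 5 and 0 adjusted over the list alone: Cdh11, a cadherin, by 0.94, Cd44 by 0.86, Zeb2 by 0.61 and Prrx1 by 0.43. That list had a camera adjusted p of 0.0398 and an adjusted p = 0.656 with an estimated correlation, and its median of −0.04 turned to 0.01 under quantile normalization and median centring. In the extracellular matrix list 3 of 42 fell and 0 rose, or 4 and 0 adjusted over the list alone: Ogn fell by 1.75, Vcan by 1.65 and Spp1 by 0.65. Medians of MEF-N4 replicates 1, 2 and 3 were 10.06, 10.18 and 9.89 for contractile genes, against 10.15, 10.03 and 10.30 in MEF-V, 8.80, 8.89 and 8.34 for fibroblast markers, against 8.97, 8.79 and 8.85, and 8.54, 8.55 and 8.19 for the extracellular matrix, against 8.65, 8.41 and 8.69. Skeletal muscle and endothelial markers had no called member by limma among 13 and 8, with 6 and 2 higher at an unadjusted p under 0.05. Their camera adjusted p-values of 0.0133 and 0.0398 were both an adjusted p = 0.656 with an estimated correlation. MEF-N4 replicate 3 lay highest in both, with medians of 6.88, 6.88 and 7.075 in replicates 1, 2 and 3 against 6.74, 6.72 and 6.68 in MEF-V for muscle markers, and of 6.25, 6.11 and 6.44 against 6.12, 6.04 and 5.985 for endothelial markers, where replicate 2 lay within MEF-V.

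In other lists fewer members were called in MEF-N4 against MEF-V. Kitl fell by 0.86, Fgf7 by 0.62 and Pdgfb rose by 0.37 among 42 growth factors and receptors, which had 4 lower and 1 higher adjusted over the list alone. Ccl2 fell by 0.71 among 21 cytokines and Hsp90aa1 by 0.80 among 10 cytosolic heat shock genes, the same count of 1 each adjusted over the list alone. Pgk1 rose by 0.41 among 26 hypoxia and glycolysis genes and Hoxc5 fell by 0.45 among 23 homeobox genes, with 0 each adjusted over the list alone. Limma called 0 of 24 ribosomal protein genes, or 3 lower adjusted over the list alone, and 0 of 11 neural markers, or 1 lower adjusted over the list alone; 6 and 1 were lower and 2 in each higher at an unadjusted p under 0.05. It called 0 members, by either adjustment, of the linker histones, matrix proteases, interferon response, antigen presentation, immediate early, unfolded protein, oxidative stress, cholesterol synthesis and oxidative phosphorylation lists, and of the adipocyte, bone and cartilage, epithelial, and macrophage and leukocyte markers. Their counts at an unadjusted p under 0.05 ran from 0 to 4 higher and from 0 to 5 lower, and their camera adjusted p-values, like those of the other lists in this paragraph, from 0.182 to 0.875. Camera did not pass the tumour suppressor, p53 target, DNA replication, extracellular matrix and contractile lists either, with adjusted p-values from 0.146 to 0.566.

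In all, limma called 714 of 15264 genes between MEF-N4 and MEF-V, 654 lower and 60 higher, and 214 of the lower but 1 of the higher changed by at least 2-fold. At an unadjusted p under 0.05 there were 3664 genes. In 24.82% of all tested genes the 2 groups did not overlap on any array, where chance gives 10%. Under quantile normalization 179 genes were higher and 685 lower, so the share of falls went from 91.6% to 79.28%. That share was 62.52% without MEF-N4 replicate 2, with 1064 higher and 1775 lower. With array weights, which rest mostly on replicate 1 for MEF-N4, it was 47.31%, so the excess of falls over rises depended on the fit. In these fits, in the order given, 643, 654 and 654 of the 654 falls were still called, but without MEF-V replicate 3 only 281 were. The count of all genes called was 330 without MEF-V replicate 2, 286 without MEF-V replicate 3, 407 without MEF-N4 replicate 1 and 2839 without MEF-N4 replicate 2, and it was 1034, 305 higher and 729 lower, without MEF-N4 replicate 3. Mrpl48 and Hoxc5, called at adjusted p-values that round to 0.05, are left out of the counts that follow. Of 48 other named genes called, 23 lost their call without MEF-V replicate 2 and 21 without MEF-V replicate 3, with adjusted p up to 0.254. Among them were ND6, Gatm, Mzf1, Cnn1, Setd2, Smarca5, Zeb2, Prrx1, Ccl2 and Fgf7. The call was lost by 17 without MEF-N4 replicate 1, 7 without MEF-V replicate 1, and 11 or 12 without an array of MEF-N2.

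**Figure D2:**
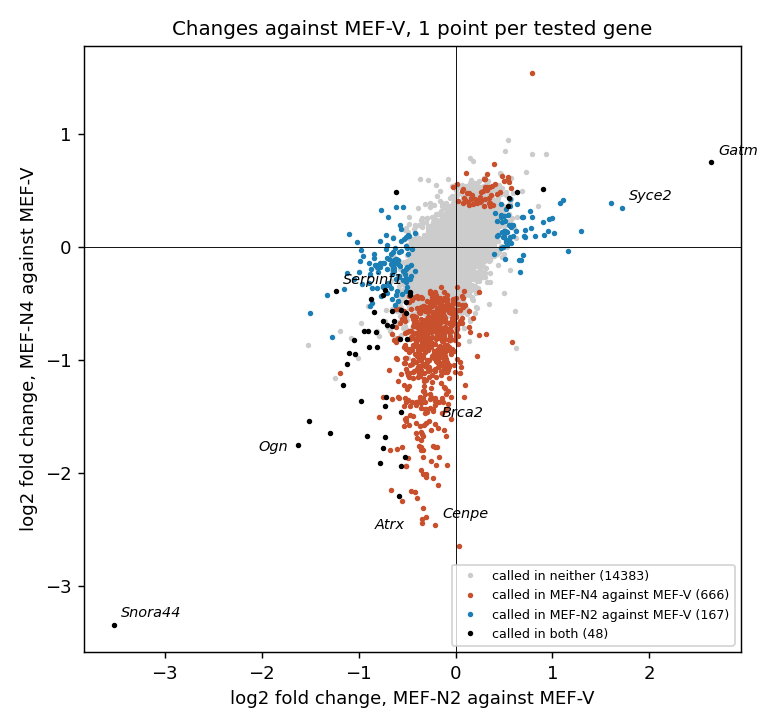
Log2 fold change against MEF-V of each of 15264 tested genes in MEF-N2 (horizontal axis) and MEF-N4 (vertical axis), 1 point per gene, coloured by the comparisons in which limma called it. Genes called in MEF-N4 lie mostly below 0, with 654 lower and 60 higher, and Snora44 was the widest fall in both comparisons, at −3.34 and −3.52.

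Comparing MEF-N2 with MEF-V asks the same question of human HMGN2. Gatm (NCBI Gene 67092, chromosome 2) rose by 2.64 ± 0.18 on the log2 scale (SE, n = 3), 6.22-fold, adjusted p = 2.67e-05, from a mean of 6.34 to 8.98. Syce2, a protein of the meiotic synaptonemal complex, rose by 1.72 ± 0.13 (SE, n = 3), 3.29-fold, and Ndn, an imprinted gene, rose by 1.61 ± 0.11 (SE, n = 3), 3.05-fold. Snora44 fell by 3.52 ± 0.22 (SE, n = 3), 11.5-fold, adjusted p = 2.67e-05. The other named rises were of Lonrf3, Renbp, Sdc3, Ildr2, Baiap2l1, S100a16 and Ripk3, a kinase of necroptosis, by 0.97 to 1.30, and the other named falls of Rps6ka6, Kcnj2, a potassium channel, Spry3, Serpinf1, Chml, Prl2c5 and Cavin2, a caveolar protein, by 1.12 to 1.497. Rps6ka6 fell to a mean of 5.269 in MEF-N2, so dim that the size of its fall is not exact.

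Some matrix and mesenchymal genes fell in MEF-N2. In the extracellular matrix list 6 of 42 genes fell and 0 rose, or 12 and 1 adjusted over the list alone: Ogn by 1.63 ± 0.23 on the log2 scale (SE, n = 3), Vcan, a large proteoglycan, by 1.30, Lox, which cross-links collagen, by 0.86 and Thbs1 by 0.49, with Tnc and Nid1 beside them. The list passed camera at an adjusted p of 5.05e-05, and its adjusted p = 0.854 with an estimated correlation. Fry gave it an adjusted p of 0.344, and in MEF-N2 against MEF-V fry passed only the fibroblast marker and antigen presentation lists. Of 20 fibroblast markers 2 fell and 0 rose, or 7 and 0 adjusted over the list alone, Cdh11 by 1.10 ± 0.12 (SE, n = 3) and Prrx1 by 0.75. Camera gave that list an adjusted p of 0.000223 and an adjusted p = 0.309 with an estimated correlation, and fry, which asks whether its members move on balance in 1 direction, gave an adjusted p of 0.0167. Adamts5 and Adam19 fell by 0.84 and 0.49 among 23 matrix proteases and inhibitors, which had 3 lower adjusted over the list alone. With the brightest probe set Cdh11 stood at 0.10 in MEF-N2 and was not called. Camera did not pass the matrix protease, growth factor, cytokine, neural, oxidative stress and bone lists in MEF-N2, with adjusted p-values from 0.129 to 0.58.

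Secreted signals and markers of other cell types moved both ways in MEF-N2. Among 42 growth factors and receptors Igfbp3 fell by 0.89, Pdgfc by 0.72 and Nrg1 by 0.60 while Pdgfb rose by 0.54, with 6 lower and 4 higher adjusted over the list alone. Among 21 cytokines the chemokine Cxcl12 fell by 0.71 and Nfkbia, the NF-kappaB inhibitor, rose by 0.55, or 2 lower and 3 higher adjusted over the list alone. H2-K1, a class I antigen gene, rose by 0.52 ± 0.10 (SE, n = 3) and was the 1 called gene of 9 in antigen presentation, or 1 of 2 such genes adjusted over the list alone. That list had a camera adjusted p of 0.00968, an adjusted p = 0.34 with an estimated correlation, and a fry adjusted p of 0.0214. Tubb3 and Map2 fell by 0.73 and 0.71 and Nes, nestin, rose by 0.69 among 11 neural markers, or 3 lower and 1 higher adjusted over the list alone. Gsta4 and Sod3 fell by 0.89 and 0.47 among 27 oxidative stress genes, with the same 2 adjusted over the list alone, and Sox9 fell by 0.65 among 11 bone and cartilage markers, the same 1 adjusted over the list alone. Rpl5, read by 1 probe set, fell by 1.09 among 24 ribosomal protein genes, or 6 lower adjusted over the list alone; that list had a camera adjusted p of 0.0147 and an adjusted p = 0.854 with an estimated correlation.

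Atm stood at −0.37 ± 0.16, Atrx at −0.35 ± 0.12 and Brca2 at −0.21 ± 0.10 against MEF-V (log2, SE, n = 3), with limma adjusted p-values of 0.283, 0.19 and 0.329; with the brightest probe set Atm stood at 0.15 and Brca2 at 0.08. Limma called 0 of 53 DNA repair genes under either adjustment, with 9 lower and 0 higher at an unadjusted p under 0.05. Camera nevertheless gave the list an adjusted p of 0.000353, with a median of −0.12 that turned to 0.03 with the brightest probe set, and its adjusted p = 0.854 with an estimated correlation. Kif20b fell by 0.58 and was the 1 called gene of 37 in mitosis by either adjustment, with a camera adjusted p of 0.00914 and an adjusted p = 0.854 with an estimated correlation. Hypoxia and glycolysis had 0 of 26 called by limma, or 1 higher adjusted over the list alone, 4 higher at an unadjusted p under 0.05, a camera adjusted p of 0.0235 and an adjusted p = 0.854 with an estimated correlation.

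In the other lists limma called 0 members in MEF-N2 against MEF-V, apart from Hmgn2 among the 9 HMG proteins, which had 1 higher and 2 lower adjusted over the list alone. Adjusted over the list alone, 1 gene was lower in cytosolic heat shock, adipocyte and macrophage lists, 1 higher in endothelial and homeobox lists, and 1 each way among contractile genes. By either adjustment 0 were called among tumour suppressors, p53 targets, DNA replication, core and linker histones, chromatin modifiers, interferon response, immediate early, unfolded protein, cholesterol synthesis and oxidative phosphorylation genes, and skeletal muscle and epithelial markers. At an unadjusted p under 0.05 these lists had from 0 to 3 genes higher and from 0 to 5 lower, and their camera adjusted p-values ran from 0.089 to 0.97.

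Limma called 215 genes between MEF-N2 and MEF-V, 148 lower and 67 higher, of which 19 and 8 changed by at least 2-fold. At an unadjusted p under 0.05 there were 2431 genes, and the groups did not overlap in 37.38% of all tested genes, where chance gives 10%. The count was 79 without MEF-V replicate 2, 49 without MEF-V replicate 3, 60, 60 and 55 without MEF-N2 replicates 1, 2 and 3, and 129, 420 and 1965 without MEF-N4 replicates 1, 2 and 3, since the spread is estimated from all 9 arrays. Represented by their brightest probe sets 31 genes were called, and Sdc3, Lonrf3, Renbp, Ildr2, Baiap2l1, S100a16, Ripk3, Rps6ka6, Kcnj2, Serpinf1, Prl2c5 and Ogn were not among them. Of 42 named genes called, 21 lost their call without MEF-V replicate 3, 14 without MEF-V replicate 2, 9 without MEF-V replicate 1, 18, 17 and 20 without MEF-N2 replicates 1, 2 and 3 and 8 without MEF-N4 replicate 1, with adjusted p up to 0.272, among them Vcan, Spry3, Chml, Thbs1, Adamts5, Cxcl12, Nfkbia, Pdgfb, Nrg1, Sod3, Rpl5 and H2-K1.

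Comparing MEF-N4 with MEF-N2 asks which genes differ between these lines, each with its own protein. Atrx differed by −2.09 ± 0.12 on the log2 scale (SE, n = 3), 4.27-fold lower in MEF-N4, with an adjusted p of 2.82e-06. Differences were −1.38 ± 0.16 for Atm, adjusted p = 0.00041, and −1.35 ± 0.10 for Brca2, adjusted p = 1.51e-05 (SE, n = 3). Rex2, dim in MEF-N4, and Cenpe, Thoc2, Nipbl, Vps13a, Arhgap5, Mki67 and Ranbp2 were also lower in MEF-N4, with differences from −2.67 to −1.82, and Gatm was lower by a difference of −1.88. The largest differences upward were of Rpl5 at 1.21, Npy1r, a neuropeptide Y receptor, at 1.10 ± 0.13 (SE, n = 3), Glipr1 at 1.10 and Tmem45a at 1.06, and Gpc4, Fhl1, Ica1, Rps6ka6, dim in MEF-N2, S1pr3 and Kcnj2 followed with 0.90 to 0.97. With the brightest probe set Atrx stood at −0.13, adjusted p = 0.829.

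Some repair and mitosis genes were called lower, and some matrix genes higher, in MEF-N4 than in MEF-N2. Of 53 DNA repair genes 9 were lower and 0 higher, or 11 and 1 adjusted over the list alone, Atr among them at −1.17. Of 37 mitosis genes 5 were lower and 0 higher, or 8 and 2 adjusted over the list alone, with Cenpf at −1.52 ± 0.11 (SE, n = 3) and Kif20b at −1.62. Camera gave both lists an adjusted p of 9.28e-05, and both had an adjusted p = 0.793 with an estimated correlation. Neither list passed fry, with adjusted p-values of 0.327 for DNA repair and 0.255 for mitosis. Their medians of −0.04 and −0.17 were 0.03 and 0.01 without MEF-N4 replicate 3; the median mitosis gene stood at 9.74, 9.90 and 9.36 in MEF-N4 replicates 1, 2 and 3, against 9.85, 9.77 and 9.74 in MEF-N2. Of 42 extracellular matrix genes 6 were higher and 0 lower, or 9 and 1 adjusted over the list alone: Fbln1 at 0.75 ± 0.11 (SE, n = 3), Fbln5 at 0.68, Thbs1 at 0.59 and Fn1, fibronectin, at 0.55, with Tnc and Nid2. That list had a camera adjusted p of 0.00426, an adjusted p = 0.793 with an estimated correlation, and a fry adjusted p of 0.382. Its median was 8.54, 8.55 and 8.19 in MEF-N4 replicates 1, 2 and 3, against 8.41, 8.48 and 8.37 in MEF-N2, so replicate 3 lay below all MEF-N2 arrays. Adamts5 was higher by 0.78 among 23 matrix proteases, or 2 adjusted over the list alone, and Ccn2 by 0.60 and Tagln by 0.65 among 24 contractile genes, or 3 adjusted over the list alone. These lists had camera adjusted p-values of 0.0291 and 0.0331, and for both the adjusted p = 0.793 with an estimated correlation.

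Further differences fell in signalling and marker lists. Pdgfc was higher in MEF-N4 by 0.83, Igfbp3 by 0.76 and Fst by 0.41, and Kitl was lower at −0.55, among 42 growth factors and receptors, or 5 higher and 3 lower adjusted over the list alone. Cxcl12 was higher by 0.73 and Cx3cl1 lower at −0.45 among 21 cytokines, or 1 higher and 3 lower adjusted over the list alone. Cxcl10 was lower at −0.66 among 22 interferon response genes, H2-K1 at −0.45 among 9 antigen presentation genes and Hsp90aa1 at −0.68 among 10 heat shock genes, with 1, 2 and 1 adjusted over the list alone. Among 23 p53 targets Cdkn1a was higher by 0.54, or 2 adjusted over the list alone; that list had a camera adjusted p of 0.0331 and an adjusted p = 0.793 with an estimated correlation. Pdgfra was higher by 0.52 and Cd44 lower at −0.43 among 20 fibroblast markers, or 3 each way adjusted over the list alone. Tubb3 was higher by 0.60 and Nes lower at −0.42 among 11 neural markers, or 2 and 1 adjusted over the list alone, with a camera adjusted p of 0.193 and a fry adjusted p of 0.0428. Skeletal muscle markers had 0 of 13 called by limma, or 1 higher adjusted over the list alone, 3 higher at an unadjusted p under 0.05, a camera adjusted p of 0.0479 and an adjusted p = 0.793 with an estimated correlation. Rps18 and Rpl5 were higher among 24 ribosomal protein genes, with 2 higher and 1 lower adjusted over the list alone, Gsta4 by 0.65 among 27 oxidative stress genes and Lpl by 0.48 among 9 adipocyte markers, each the same 1 adjusted over the list alone. Lower were Apc at −0.995 among 30 tumour suppressors, or 1 each way adjusted over the list alone, Pola1 at −1.33 and Ccne2 at −0.64 among 36 replication genes, the same 2 adjusted over the list alone, Tet2 at −0.58 among 55 chromatin modifiers, or 0 adjusted over the list alone, and Hmgn2 among 9 HMG proteins, or 2 adjusted over the list alone. Limma called 0 members of the core histone, linker histone, immediate early, unfolded protein, hypoxia, cholesterol and oxidative phosphorylation lists and of the bone, epithelial, endothelial, macrophage and homeobox lists, or 1 core histone lower and 1 bone gene higher adjusted over the list alone, with 0 to 4 higher and 0 to 4 lower at an unadjusted p under 0.05. The lists that did not pass camera between MEF-N4 and MEF-N2 had adjusted p-values from 0.112 to 0.953.

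Limma called 476 genes between MEF-N4 and MEF-N2, 368 lower and 108 higher in MEF-N4, of which 115 and 4 differed by at least 2-fold. At an unadjusted p under 0.05 there were 1946 genes, and the groups did not overlap in 17.13% of all tested genes, where chance gives 10%. Under quantile normalization 217 were higher and 432 lower, so the share of falls went from 77.31% to 66.56%. With array weights, which rest mostly on replicate 1 for MEF-N4, 1368 were higher and 1295 lower. The count was 203, 235 and 214 without MEF-N2 replicates 1, 2 and 3 and 254, 1137 and 935 without MEF-N4 replicates 1, 2 and 3, the last with 459 higher and 476 lower. Of 54 named genes called, 14 to 18 lost their call without MEF-N4 replicate 1 or an array of MEF-N2, with adjusted p up to 0.21, and 8 or 9 without an array of MEF-V, among them Rps6ka6, Cdkn1a, Tet2, Fn1, Fbln5, Adamts5, Pdgfra, Fst, Kitl, Lpl, H2-K1, Cx3cl1 and Nes.

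**Figure D3:**
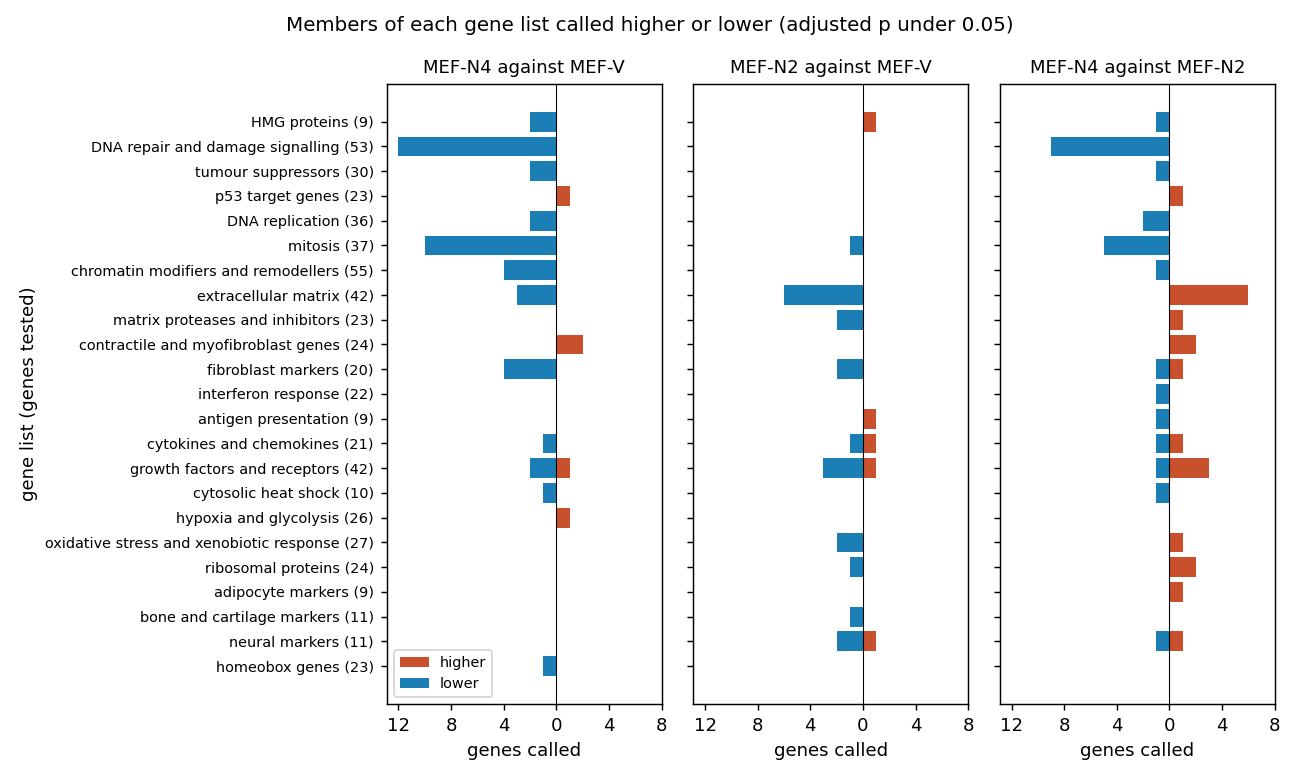
Number of members of each gene list that limma called higher (right of 0) or lower (left of 0) at an adjusted p threshold of 0.05, for each of the 3 comparisons, with the number of tested genes after each list's name; lists without a called member in any comparison are left out. DNA repair had 12 lower in MEF-N4 against MEF-V and 9 lower against MEF-N2, and the extracellular matrix had 6 lower in MEF-N2 against MEF-V and 6 higher in MEF-N4 against MEF-N2.

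Changes against MEF-V were compared between the lines, with the same 3 control arrays in both comparisons, which by itself makes changes go together. Ogn, Vcan, Cdh11, Prrx1, Kif20b and Snora44 fell in both MEF-N2 and MEF-N4, and Gatm and Pdgfb rose in both. Leaving out 1 array ended some of these calls, with adjusted p up to 0.272: those of Pdgfb and Prrx1 in both lines, of Gatm in MEF-N4 and of Vcan and Kif20b in MEF-N2. Called lower in both were 42 genes and called higher in both 5, and the overlap that shared controls give was not computed. Across genes, which are not independent replicates, the 2 sets of changes had a Pearson r of 0.624, with a jackknife SD of 0.110 over arrays left out, and a Spearman rho of 0.694. Unchanged groups set against a shared simulated control gave an r of 0.501 and at most 0.518, below the lowest r of 0.554 over the alternatives run. Their covariance was 0.0081 where 0.0394 was observed. The simulation left out correlation between genes and gave all 3 groups the same spread, while weights of the real arrays ran from 0.11 to 3.508. The r that unchanged groups of unequal spread would give is not known. Since 0.624 also exceeds 0.501 by little more than the jackknife SD, whether the lines share a response beyond the controls was not settled. Of the 654 genes lower in MEF-N4, 614 lay below 0 in MEF-N2 as well, with a median of −0.26 against −0.82, and 296 were also called lower in MEF-N4 than in MEF-N2. The moderated F test called 810 genes among the 3 groups, and 445 without MEF-V replicate 2, 404 without MEF-V replicate 3, 453, 484 and 483 without MEF-N2 replicates 1, 2 and 3, and 473, 2212 and 2307 without MEF-N4 replicates 1, 2 and 3.

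Chromosome medians were compared since immortalized lines can differ in copy number. In MEF-N2 against MEF-V the largest shift was on chromosome 2, whose 1229 genes lay 0.09 below all tested genes on the log2 scale, a shift of −0.09 with an adjusted p of 5e-05, and chromosome 12 lay 0.07 above. In MEF-N4 against MEF-V chromosome 7 shifted by 0.04 and chromosome 13 by −0.04, with adjusted p-values of 0.0002 and 0.0107 in permutation tests. The permutation test passed 12 of 20 chromosomes in MEF-N2 against MEF-V, 4 in MEF-N4 against MEF-V, or 2 without MEF-V replicate 2, and 8 in MEF-N4 against MEF-N2, and no shift exceeded 0.085. It treats genes as independent, which neighbours are not, and the smallest p it can give is 1e-05.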

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

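The counts of other splits given here were chosen before the data were examined. With 3 arrays per group the rule for outlying arrays could not be applied, and MEF-N4 replicate 3 was examined by other tests.

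MEF-N4 and MEF-N2 differed in 476 genes when tested against each other, a difference between lines that need not come from the proteins. Of these, 368 were lower in MEF-N4 and 108 higher, Atrx at −2.09, Cenpe at −2.25 and Mki67 at −1.84 among the lower. The splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05, and the real split gave 476 genes where the highest of the others gave 0. For MEF-N4 against MEF-V these values were 714 and 0, and for MEF-N2 against MEF-V 215 and 1, again 1 of 10 splits in each case. For the F test over 3 groups, 1 of 100 splits, the real one with its 810 genes, gave as many, the highest of the others giving 249. This argues against a random grouping of these arrays. It cannot address chance differences between cultures, since the labels do not say whether the replicates were separate cultures.

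Npy1r, a neuropeptide Y receptor, was the 1 gene called in opposite directions against MEF-V. It rose in MEF-N4 by 0.49 ± 0.13 and fell in MEF-N2 by 0.61 ± 0.13 on the log2 scale (SE, n = 3), with limma adjusted p-values of 0.0473 and 0.0359. The direct difference was 1.105, adjusted p = 0.000382, and with the brightest probe set its adjusted p was 0.0794.

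Probe sets that named no gene or several genes were in no comparison of genes, and 717 of 18147 tested were called in MEF-N4 against MEF-V. Of these, 692 were lower and 25 higher, against 7 called in MEF-N2 against MEF-V and 335 in MEF-N4 against MEF-N2. The share called in MEF-N4 against MEF-V was 3.95%, and 2.51% of the probe sets that named 1 gene were called in the same fit.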

How the results depend on the processing

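All alternatives were chosen before the data were examined, but the gene by gene method for array weights was taken after the default did not converge. Of the named genes called, 22 of 48 in MEF-N4 against MEF-V, 6 of 42 in MEF-N2 against MEF-V and 24 of 54 in MEF-N4 against MEF-N2 kept their call under all alternatives run per gene. Of those not called, 23 of 40, 30 of 47 and 11 of 29 gained one under some. Mrpl48 and Hoxc5, called in MEF-N4 against MEF-V at adjusted p-values that round to 0.05, were counted here among the 40 not called. Other genes are named next. Cenpe, Nipbl, Mki67, Atm, Brca2 and Acta2 kept their calls in MEF-N4 against MEF-V under all alternatives run per gene, with Atm between −1.94 and −1.54. The correlation of the changes in MEF-N2 and MEF-N4 ran from 0.554 to 0.706, within its jackknife SD of 0.110. Median centring, no filter, the 50th percentile filter and the trended variance left each total of genes called within 1.5 times, but median centring took the genes called higher from 60 to 126 in MEF-N4 against MEF-V and from 108 to 187 in MEF-N4 against MEF-N2. Numbers of replicates did not pair the arrays: 0 of 9 had their highest correlation outside their group with their own number, and a replicate block gave 580, 103 and 371 genes for MEF-N4 and MEF-N2 against MEF-V and MEF-N4 against MEF-N2. Brightness over background could not be set without detection calls, which limits what is said of dim genes.

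In the order MEF-N4 against MEF-V, MEF-N2 against MEF-V, MEF-N4 against MEF-N2 and genes differing among the 3 groups, the counts were 268, 31, 232 and 298 with the brightest probe set, 440, 94, 289 and 487 with the median probe set, and 3441 (1813 higher, 1628 lower), 2856, 2663 and 4982 with array weights, where MEF-N4 replicate 3 had a weight of 0.11. Fits of only the 6 arrays compared, which lose residual arrays or a group of wider spread, gave 357, 2203 and 248. A threshold of 0.1 gave 1191 and 390 genes against MEF-V, and for MEF-N2 quantile normalization gave 345, a minimum of 1.5-fold 137 and probe sets tested alone, many more tests, 45. Leaving out 1 array at a time gave 286 to 2839, 49 to 1965, 203 to 1137 and 404 to 2307. Lists past camera were 4, 3 and 5 in MEF-N4 against MEF-V with the 50th percentile filter, brightest and median probe sets and 5 to 8 with 1 array left out; 3 and 4 in MEF-N2 against MEF-V with brightest and median probe sets; and 2 in MEF-N4 against MEF-N2 with the brightest, and 2 to 7 with 1 array left out. Chromosomes past the test in MEF-N4 against MEF-V were 2 without the filter and 2 to 5 with 1 array left out. Apart from fits with fewer arrays or more tests, the cause was not tested.

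Directions turned mostly with the brightest probe set. In MEF-N4 against MEF-V these stood at 0.43 for Hmgn1, 0.22 for Hmgn2, 0.22 for Zeb2, 0.39 for Ddx58, −0.10 for Tap2, 0.032 for Rpl10a and 0.019 for the chromatin list. In MEF-N2 against MEF-V they stood at 0.15 for Atm, 0.076 for Brca2, 0.049 for Prkdc, 0.12 for Trp53inp1, 0.048 for Mcm4, 0.26 for Smarca5, 0.10 for Cdh11, 0.01 for Myc, 0.15 for Nr4a2, 0.10 for Lpl, 0.027 for the DNA repair list and 0.012 for mitosis. In MEF-N4 against MEF-N2 Lpl stood at −0.175 and matrix proteases at −0.023. With the median probe set Hmgn3 was 0.15 and Dlx5 −0.075 in MEF-N4 against MEF-N2, and H1f10 −0.16 and Cd14 0.083 in MEF-N2 against MEF-V. The fibroblast marker median in MEF-N4 against MEF-V was 0.013 under quantile normalization, 0.009 under median centring, 0.022 without the filter, 0.024 with the median probe set, and −0.10 to 0.00 with 1 array left out. Left out in turn, arrays gave −0.15 to 0.011 for the chromatin list and −0.20 to 0.049 for Hmgn1 in MEF-N4 against MEF-V. Against MEF-N2 they gave −0.12 to 0.032 for the DNA repair list, −0.295 to 0.009 for mitosis, −0.19 to 0.087 for Hmgn3, −0.30 to 0.001 for Ndufa2 and −0.049 to 0.31 for Dlx5. The cause was not tested.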

Other observations

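The tests of MEF-N4 replicate 3 carrying the fall, of transcript size alone, of whole transcripts at a lower level and of an array of another group were chosen after the result was seen, as were the windows and classes singled out below.

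A stretch of chromosome 2 was lower in MEF-N2. In windows of 50 neighbouring genes, the widest shift there ran from Kcnj3 to Dlx1. Its median change against MEF-V, less that of all tested genes, was −0.25 on the log2 scale. Of the 50 genes 38 lay below 0, and 1 of the 50 was called. All window values given here, those per array included, are relative to the median of all tested genes. The median stood at −0.21, −0.22 and −0.21 in MEF-N2 replicates 1, 2 and 3, at −0.02, 0.00 and 0.02 in MEF-V and at −0.09, −0.03 and −0.28 in MEF-N4. On this chromosome 178 windows passed the 95% threshold of the largest window in 1000 permutations, and the widest had p = 0.001, the smallest these permutations can give. MEF-N4 against MEF-V had its own window on chromosome 2, from Pdcl to Baz2b, at −0.18 with p = 0.047 in the permutation test. That window stood at −0.12, −0.15 and −0.19 in MEF-N2 replicates 1, 2 and 3. In MEF-N4 the widest shift on chromosome 13 ran from Exoc3 to Homer1, at −0.29, with −0.25, −0.15 and −0.39 in MEF-N4 and −0.02, −0.13 and −0.04 in MEF-N2. That on the X chromosome ran from Zmym3 to Tspan6, at −0.33, with −0.26, −0.14 and −0.37 in MEF-N4, but also −0.13, −0.17 and −0.15 in MEF-N2, which had its own X window, from Magee1 to Tceal8, at −0.24. Windows on chromosomes 4, 11 and 14, at −0.26, −0.22 and −0.23 in MEF-N4 against MEF-V, had the same p = 0.001 in the permutation test. They were low in MEF-N2 replicates 1, 2 and 3 too, at −0.14, −0.20 and −0.16 on chromosome 4, −0.135, −0.21 and −0.16 on 11, and −0.09, −0.12 and −0.09 on 14. MEF-N2 had its own windows on chromosomes 4 and 11, at −0.20 and −0.23. Permuted genes lose the correlation of neighbours, so these p-values are lower bounds.

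Genes with many probe sets were called lower in MEF-N4 more often. Of genes with 1 probe set 3.13% were called lower, of those with 21 to 30 9.9% and of those with over 30 13.97%. Within the mitosis list, 26 genes with over 10 probe sets had a median of −0.35 and 10 calls, Cenpe, Cenpf and Kif20b among them, while 11 genes with at most 10 had a median of −0.07 and 0 calls by limma. DNA repair genes with at most 10 were lower as well, with a median of −0.13 (95% interval −0.27 to −0.02) and 1 call, against −0.25 and 11 calls for those with over 10. Spearman's rho between change and probe set number across the list was −0.519, adjusted p = 0.0009 in a permutation test, and −0.492, adjusted p = 0.0009, across the DNA repair list, but −0.007, adjusted p = 0.967, across DNA replication. Genes are not independent replicates, the interval comes from draws of genes and not of arrays, and a mean over more probe sets also has less error.

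The fall of 654 genes in MEF-N4 was set against technical and biological explanations. Against MEF-N4 replicate 3 alone carrying the fall, 729 genes were lower without it, but 281 were lower without MEF-V replicate 3, 325 without MEF-V replicate 2 and 395 without MEF-N4 replicate 1, so the part of these arrays stays open. Against transcript size alone, 2225 genes with over 20 probe sets had a median of −0.04 (95% interval −0.05 to −0.03), and against fewer dividing cells as the whole cause, the mitosis genes with at most 10 probe sets had a median of −0.071 (95% interval −0.09 to 0.09). Both intervals come from draws of genes and leave out the spread between arrays. Classes of all tested genes with at most 10 probe sets had medians of 0.05 to 0.095, so these mitosis genes lay below genes of like size. The 10 called mitosis genes all had over 10 probe sets and were not in this class. A part for fewer dividing cells therefore stays open. Medians of all tested genes against the MEF-V mean were 0.056, 0.06 and −0.062 in MEF-N4 replicates 1, 2 and 3. Whole transcripts at a lower level stay open: within 333 called genes the probe set at 1 end stood 0.471 above interior ones of like brightness, and in 32 genes lower in MEF-N2 alone it stood 0.462 above, so a weak response of probe sets at 1 end to any change cannot be told apart from shortened transcripts. An effect of HMGN4 itself also stays open, as does a difference between separately derived lines, and neither was tested.

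MEF-N4 replicate 3 stood apart from the other 8 arrays. A narrower spread of its values alone is argued against by a median rank correlation of 0.908 with the other arrays, the lowest of the others being 0.97, since a change of scale leaves ranks as they are. An array of another group is argued against too: of 70 genes that replicates 1 and 2 of MEF-N4 put at least 2-fold below both other groups, 100% lay below all 6 arrays of those groups in replicate 3. Differences in RNA quality or handling of this array stay open, since the labels give no batch or quality value. No biological explanation was tested.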
